A study of Mus musculus with 10 samples.

How the data were processed

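RNA of sorted CD4+ Foxp3+ regulatory T cells (Tregs) was measured on 10 Affymetrix Mouse Gene 1.0 ST arrays, 1 array per library. The cells came from spleen and lymph node of female C57Bl/6 mice aged 7 weeks. Genotype (PTEN-deficient or wild type, WT) and gate (CD25+ or CD25-) gave 4 groups: 3 PTEN-deficient CD25+ arrays (replicates 1, 2 and 3), 2 PTEN-deficient CD25- arrays (replicates 1 and 3), 2 WT CD25+ arrays (replicates 1 and 3) and 3 WT CD25- arrays (replicates 1, 2 and 3). Groups and replicate numbers were taken from the sample titles, and no array was moved to another group.

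The deposited values are intensity on a linear scale, which per the labels the authors made with Affymetrix Power Tools and RMA. The versions of both are not given in the sources used here. RMA values are usually deposited as log2, and the design assumed this, but the values reached 18651 with array medians of 72.9 to 79.2, so log2 was taken before any test. No probe set was left out for dim signal, since the table holds no detection calls, and the number of arrays limits the precision of every value.

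Of 24922 probe sets, the platform table paired 21425 with exactly 1 gene symbol, 1399 with several and 2098 with none. For 21347 of the 21425 the gene identifier was found in the mouse annotation, and 0 symbols changed. The tests used 19752 genes; for the 921 with several probe sets, the one with the highest mean over all 10 arrays was taken. The 3497 probe sets with several symbols or none were tested apart. Pten had 0 probe sets paired with it alone, so its expression is not analysed here.

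Differences were tested in limma 3.58.1 under R 4.3.3. A linear model with 4 group means was fitted to log2 values of all 10 arrays (6 residual degrees of freedom), followed by empirical Bayes moderation and two-sided tests. The Benjamini-Hochberg adjustment ran over all genes within a contrast, and the threshold was an adjusted p of 0.05 with no minimum fold. There were 6 contrasts: PTEN-deficient minus WT in each gate, CD25- minus CD25+ in each genotype, the genotype difference averaged over both gates, and the interaction, which is the genotype difference in CD25- cells minus that in CD25+ cells. An exact two-sided test of 3 arrays against 2 cannot give a p below 0.2, and one of 5 against 5 cannot go below 0.00794, which is why a model sharing its spread across groups and genes was used. Errors beside group means are SD, and errors beside log2 differences are the moderated SE.

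The groups, contrasts, threshold, naming rule, gene lists and all alternatives but 1 were fixed before the data were examined. Genes were named by this rule: Foxp3 and Il2ra in every contrast; then up to 8 per direction with the largest log2 change among genes past the threshold whose groups did not overlap, leaving out predicted, small RNA, immunoglobulin, T cell receptor, olfactory, vomeronasal, histone and ribosomal protein genes; the 5 with the smallest p per direction where 0 passed; and members with the smallest p of each gene list that passed. Of each list of other cell types, the members with the largest difference were named. Any other gene is said to have been chosen after its values were seen.

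The 26 gene lists held 502 genes, of which 456 were measured. They were Treg core signature, effector Treg, resting and naive T cell, follicular T cell, Th1 and cytotoxic, Th2, Th17, cell cycle, PI3K-AKT-mTOR components, FOXO1 targets in T cells, glycolysis, sterol and fatty acid synthesis, oxidative phosphorylation, IL-2 and STAT5, interferon-stimulated, immediate early and sorting stress, co-inhibitory receptors, BCL2 family, chemokine receptors and homing, conventional T cell genes low in Treg, and 6 lists of other cells (B cell, plasma cell, myeloid and dendritic, CD8 and NK cell, erythroid and platelet, stromal and endothelial markers). Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjusted p over the 26 lists of a contrast, and again with an estimated correlation. Lists share members, so they are not independent tests.

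A gate score placed each array between the WT gates. The 50 genes for it were chosen on the WT arrays alone, and each gene was scaled so that the WT CD25+ mean was 0 and the WT CD25- mean was 1. The WT arrays' own scores are therefore set by construction.

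Alternatives were: only the brighter genes, the mean of a gene's probe sets, a shift of each array to a common median, quantile normalization, a trended and robust variance model, array weights, only the arrays of the groups compared, the replicate number as a fixed block, genotype and replicate number together as a random block, and each array left out in turn. Array weights were computed gene by gene because the default estimate did not converge. An alternative without both PTEN-deficient replicate 1 libraries was added after the data were seen. It leaves 8 arrays with 4 residual degrees of freedom, and its lone PTEN-deficient CD25- library is assumed to vary like the other groups.

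The fits were tested on simulated data with the same layout. With 200 of 19752 genes changed by 1 or 2 on the log2 scale, the share of the genes changed by 1 that was recovered was 92, 89, 86, 91, 54 and 99% over the 6 contrasts with 10 arrays (in the order CD25+ genotype, CD25- genotype, WT gate, PTEN-deficient gate, interaction, averaged genotype). With 8 arrays it was 95, 83, 97, 79, 26 and 100%. Each gene's simulated spread was its moderated residual spread in these arrays, drawn independently between genes. The shares therefore hold for independent noise of that size and for 200 changed genes, and not for noise shared between genes. Figures were drawn in matplotlib 3.10.9 under Python 3.11.15.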

Results

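The series profiled Foxp3+ CD4+ regulatory T cells (Tregs) of PTEN-deficient and wild-type (WT) mice on whole-transcript arrays. PTEN is a lipid phosphatase that opposes PI3K signalling, and CD25, encoded by Il2ra, is the alpha chain of the IL-2 receptor. Cells were sorted from spleen and lymph node as CD25+ or CD25-. There were 10 arrays: 3 PTEN-deficient CD25+, 2 PTEN-deficient CD25-, 2 WT CD25+ and 3 WT CD25-. Median intensity ran from 72.9 to 79.2 per array, and the number of arrays limits the precision. Pten itself had no probe set of its own, so it gave no check of the genotype labels. The labels speak of 3 separate mice but do not say which animal gave which array, so the p-values measure the spread between these samples.

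Foxp3, the transcription factor that defines Tregs, was bright in every library, between 11.08 and 11.78 on the log2 intensity scale. Its group means were 11.38 ± 0.13 (SD, n = 3) in PTEN-deficient CD25+, 11.57 ± 0.30 (SD, n = 2) in PTEN-deficient CD25-, 11.36 ± 0.04 (SD, n = 2) in WT CD25+ and 11.25 ± 0.15 (SD, n = 3) in WT CD25- cells. Il2ra followed the sort in WT cells, at 12.69 ± 0.05 (SD, n = 2) in CD25+ and 10.58 ± 0.76 (SD, n = 3) in CD25-. In the PTEN-deficient groups the spread was wider, at 12.11 ± 1.08 (SD, n = 3) for libraries labelled CD25+ and 11.76 ± 1.29 (SD, n = 2) for those labelled CD25-. The library labelled PTEN-deficient CD25+ replicate 1 had an Il2ra of 10.86, against 12.77 and 12.70 in replicates 2 and 3. The library labelled PTEN-deficient CD25- replicate 1 had 12.67, against 10.84 in replicate 3.

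The same 2 libraries stood out over 50 genes that separate the gates in WT arrays, on a score that puts the WT CD25+ mean at 0 and the WT CD25- mean at 1. The library labelled PTEN-deficient CD25+ replicate 1 had a median score of 0.983, with 49 of 50 genes nearer the WT CD25- mean. The one labelled PTEN-deficient CD25- replicate 1 had 0.191, with 11 of 50 nearer that mean. The other libraries labelled PTEN-deficient CD25+ scored -0.042 and 0.134, and the other one labelled CD25- scored 1.01. All 10 labels were kept. Each comparison is therefore also given without this pair of libraries, an alternative chosen after the data were seen.

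**Figure D1:**
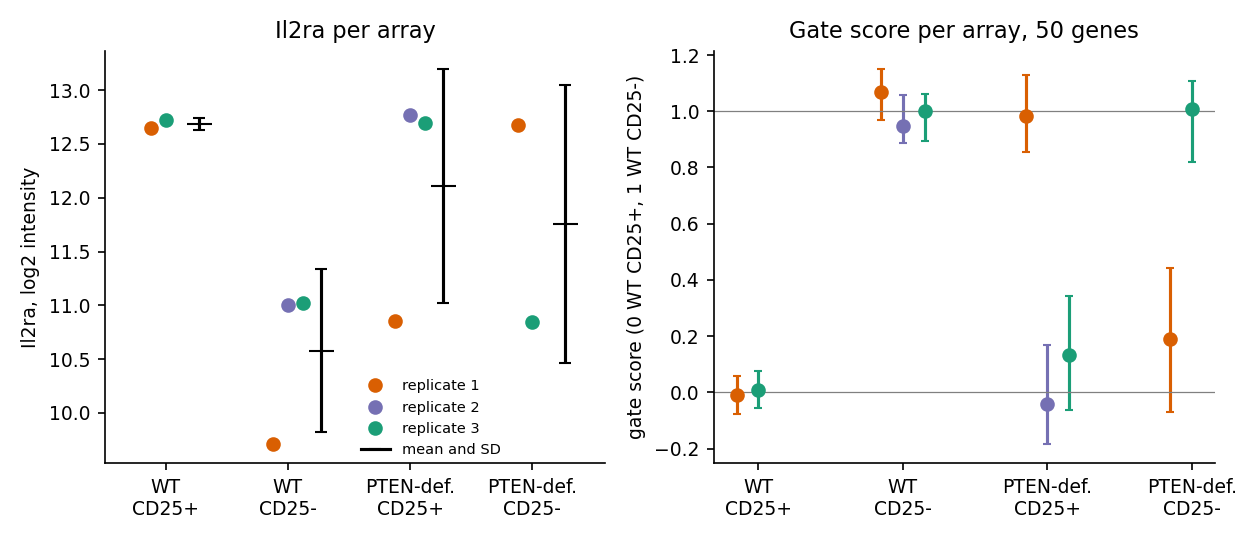
Log2 intensity of Il2ra (left; black marks are the group mean and SD) and the gate score over 50 genes (right; points are medians and bars the quartiles over the genes) for each of the 10 arrays. In both panels PTEN-deficient replicate 1 has the library labelled CD25+ at the level of WT CD25- arrays (Il2ra 10.86, score 0.983) and the one labelled CD25- near WT CD25+ arrays (12.67, 0.191).

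What PTEN deficiency changed in Tregs of both gates was tested by the genotype difference averaged over the gates, 5 arrays against 5. Of 19752 genes, 2 passed in limma, both lower without PTEN, and 608 had an unadjusted p under 0.05 where chance gives 987.6. Dapl1, a transcript of resting T cells, fell by 1.84 ± 0.16 (log2, SE, adjusted p 0.00666), from 10.52 ± 0.26 (SD, n = 5) in WT to 8.69 ± 0.36 (SD, n = 5) in PTEN-deficient libraries. Il7r, the IL-7 receptor alpha chain and a target of FOXO1, which PI3K signalling excludes from the nucleus, fell by 1.03 ± 0.10 (SE, adjusted p 0.00695), from 11.62 ± 0.19 (SD, n = 5) to 10.61 ± 0.09 (SD, n = 5). The folds weigh both gates equally while these means pool 5 arrays, so the 2 differ slightly. For both genes all 5 PTEN-deficient arrays lay below all 5 WT arrays. The genotypes lay apart in either direction for 0.435% of all genes, where chance gives 0.794% on average. The naming rule asks for this gap, so it adds no support. Neither reduction was shown to differ between the gates, with an interaction of -0.58 ± 0.33 (SE, adjusted p 1) for Dapl1 and 0.17 ± 0.20 (SE, adjusted p 1) for Il7r. Without the replicate 1 pair Dapl1 was -1.74 ± 0.18 (SE, adjusted p 0.0831) and Il7r -1.0 ± 0.12 (SE, adjusted p 0.108), 0 genes passed in limma and 688 had an unadjusted p under 0.05. Both genes also lost the call without the library labelled PTEN-deficient CD25- replicate 1, or without WT CD25+ replicate 1, with adjusted p up to 0.0689 for Dapl1 and 0.119 for Il7r. Il7r alone lost it without PTEN-deficient CD25- replicate 3 or WT CD25+ replicate 3.

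**Figure D2:**
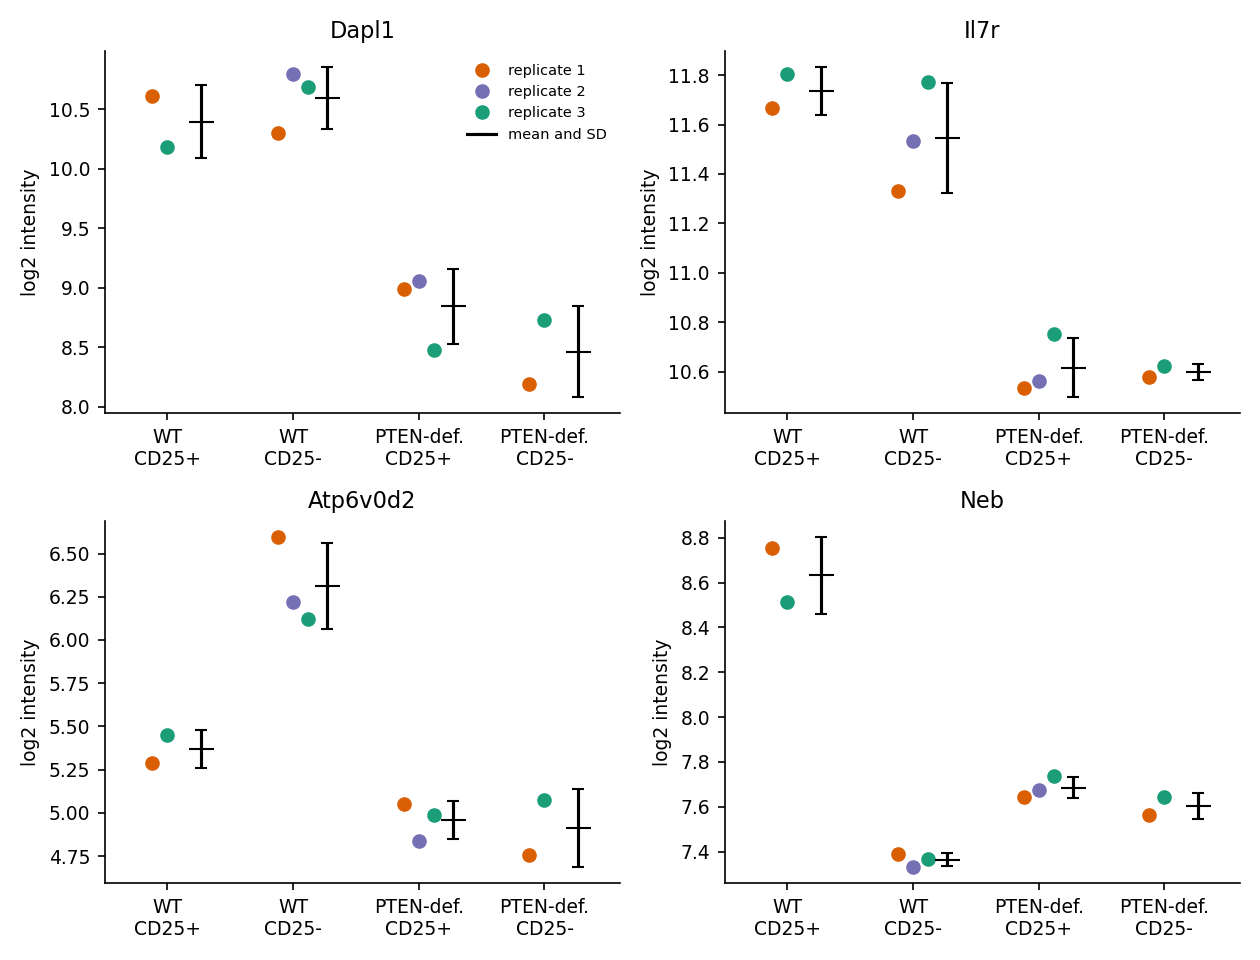
Log2 intensity per array of the 4 genes that passed the threshold in any comparison of the 10 arrays, by group; black marks are the group mean and SD, and axes do not start at 0. Dapl1 lies between 8.19 and 9.06 in PTEN-deficient and between 10.18 and 10.80 in WT libraries, and Il7r between 10.54 and 10.75 and between 11.33 and 11.80.

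Around these genes, most resting T cell genes were lower and most cell cycle genes higher in PTEN-deficient libraries. With the estimated correlation 0 lists passed in this contrast. Of 19 resting and naive T cell genes, 18 were lower and 1 higher, with a median log2 difference of -0.24 (camera adjusted p 4.49e-15, and adjusted p 0.155 with the estimated correlation). Over all genes 2 of them passed (Dapl1 and Il7r), and adjusted over the list alone 8 passed, all lower: Satb1, Klf2, Il7r, Dapl1, Actn1, Pik3ip1, Txk and Klf3. Satb1, a chromatin organiser repressed by Foxp3, was at -0.39 ± 0.11 (SE), and Pik3ip1, an inhibitor of PI3K, at -0.42 ± 0.15 (SE). FOXO1 targets were lower in 15 of 18 (median -0.16, adjusted p 1.8e-05, and adjusted p 0.212 with the estimated correlation), and Il7r passed both over all genes and adjusted over the list alone. Cell cycle genes were higher in 35 of 39 (median 0.20, adjusted p 2.98e-14, and adjusted p 0.215 with the estimated correlation). Among them were Mcm3 at 0.40 ± 0.12 (SE), Bub1 at 0.55 ± 0.24 (SE) and Ccnb2 at 0.35 ± 0.13 (SE), with 0 past the threshold in limma over all genes and 0 adjusted over the list alone. Without the pair the resting and naive list was at -0.31 (adjusted p 1.4e-24, or adjusted p 0.188 estimated), FOXO1 targets at -0.31 (adjusted p 4.86e-10, or adjusted p 0.215 estimated) and cell cycle at 0.12 (adjusted p 0.000144, or adjusted p 0.427 estimated).

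Averaged over the gates, the Treg core signature was higher in PTEN-deficient libraries, in 23 of 27 genes (median 0.23, adjusted p 9.93e-09, and adjusted p 0.212 with the estimated correlation). With all arrays it was called in the CD25- gate and not in the CD25+ gate (interaction median 0.35, camera adjusted p 0.00019). The CD25- group holds the library labelled replicate 1, whose Il2ra was 12.67. In the average Penk, which encodes proenkephalin, had 1.30 ± 0.19 (SE, adjusted p 0.163) and was the 1 member past the threshold adjusted over the list alone, against 0 over all genes. Tnfrsf18 was at 0.35 ± 0.11 (SE), Tnfrsf9 at 0.48 ± 0.15 (SE), Foxp3 at 0.17 ± 0.11 (SE) and Il2ra at 0.30 ± 0.46 (SE). Conventional T cell genes that Tregs keep low were lower still in 13 of 19 (median -0.091, adjusted p 0.00371, and adjusted p 0.312 with the estimated correlation), with 2 past the threshold over all genes and 3 adjusted over the list alone (Satb1, Dapl1 and Il7r). Oxidative phosphorylation (median 0.079, adjusted p 0.00164), co-inhibitory receptors (0.078, adjusted p 0.0124), IL-2 and STAT5 (0.084, adjusted p 0.0382) and glycolysis (0.087, adjusted p 0.0488) were called higher. With the estimated correlation their adjusted p were 0.484, 0.312, 0.442 and 0.78. Over all genes 0 of their members passed, and adjusted over the list alone only Cd160 did, a co-inhibitory receptor at 0.76 ± 0.18 (SE). Glycolysis lost the call without the pair, at 0.079 (adjusted p 0.177), as did IL-2 and STAT5 at 0.056 (adjusted p 0.549).

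Of the remaining lists of T cell state and metabolism, 11 were not called in the averaged contrast. Their medians were 0.074 for interferon-stimulated genes (adjusted p 0.0563), 0.034 for follicular T cell (adjusted p 0.0916), 0.019 for effector Treg (adjusted p 0.114), -0.054 for Th17 (adjusted p 0.134) and -0.082 for chemokine receptors and homing (adjusted p 0.281). They were -0.016 for PI3K-AKT-mTOR components and -0.049 for immediate early and sorting stress (adjusted p 0.304 each), -0.043 for the BCL2 family (adjusted p 0.451), -0.020 for Th1 and cytotoxic (adjusted p 0.463), -0.027 for Th2 (adjusted p 0.822) and -0.011 for sterol and fatty acid synthesis (adjusted p 0.83). For the last 3 the test pointed up although the median was below 0, and for Th1 and Th2 the mean was above 0. Among these lists, Ccr8 passed adjusted over the Th2 and the chemokine list alone, Gpr15 over the chemokine list alone and Scd2 over the sterol list alone. In every called list of all 10 arrays the median, the mean and the test had 1 sign. Without the pair the effector Treg, follicular T cell, Th1 and cytotoxic and interferon-stimulated lists were called higher, at 0.050, 0.16, 0.11 and 0.079 (adjusted p 0.00321, 3.4e-05, 0.0467 and 0.0417). PI3K-AKT-mTOR components, immediate early and sorting stress and chemokine receptors and homing were called lower, at -0.073, -0.088 and -0.11 (adjusted p 0.0118, 0.0153 and 0.0106). The smallest adjusted p of these 7 with the estimated correlation was 0.355.

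Transcripts of other cells were tested in the same contrast. Of the 6 lists, plasma cell markers were called higher (8 of 11, median 0.069, adjusted p 0.0216) and erythroid and platelet markers lower (7 of 7, median -0.098, adjusted p 0.00167), each with an adjusted p of 0.212 with the estimated correlation and 0 members past the threshold over all genes. Slamf7, a surface receptor of plasma cells and some T cells, had 0.60 ± 0.11 (SE, adjusted p 0.292) and was the 1 member past the threshold adjusted over the list alone. Ppbp, a platelet chemokine, was at -0.51 ± 0.16 (SE). The other 4 lists were not called: B cell markers at -0.043 (adjusted p 0.47), myeloid and dendritic markers at -0.020 (adjusted p 0.863), CD8 and NK cell markers at 0.023 (adjusted p 0.367) and stromal and endothelial markers at -0.034 (adjusted p 0.304). The mean was above 0 for B cell and myeloid markers. The largest single value among them was Lyz2, the macrophage lysozyme, at 0.83 ± 0.23 (SE), with the 5 PTEN-deficient arrays above the 5 WT arrays. Over all genes 0.435% lay apart in either direction, where chance gives 0.794% on average. The brightest members over all 10 arrays were Cst3 at 10.17, Xbp1 at 10.09, Pecam1 at 9.46, Cd8b1 at 9.21, Cd74 at 8.72 and Slc4a1 at 6.30 (mean log2 intensity). For each of these lists but the plasma cell markers, the median member lay below the median of all genes on every array. Of the plasma cell markers 3 of 11, among them Xbp1, and of the CD8 and NK cell markers 3 of 14 also belong to lists outside these 6. A sort on CD4 and Foxp3 is meant to leave out all 6 cell types.

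In libraries labelled CD25+, the question was what PTEN loss changed in the classical Treg population. The genes with the smallest p were lower without PTEN: Neb, which encodes the sarcomere protein nebulin, was closest to the threshold at -0.95 ± 0.11 (SE, adjusted p 0.0807), followed by Il7r at -1.12 ± 0.14 (SE, adjusted p 0.086), Dapl1 at -1.55 ± 0.23 (SE, adjusted p 0.277) and Prg4 at -1.03 ± 0.18 (SE, adjusted p 0.761). Neb was 7.69 ± 0.05 (SD, n = 3) in PTEN-deficient and 8.63 ± 0.17 (SD, n = 2) in WT libraries, and Il7r 10.62 ± 0.12 (SD, n = 3) and 11.73 ± 0.10 (SD, n = 2). On the higher side stood Actg2 at 1.01 ± 0.22 (SE), E2f2, a transcription factor of the cell cycle, at 0.57 ± 0.13 (SE) and B3gnt3 at 0.54 ± 0.13 (SE). Il2ra was at -0.58 ± 0.65 (SE) and Foxp3 at 0.02 ± 0.15 (SE). In limma 0 genes passed, and 529 had an unadjusted p under 0.05 where chance gives 987.6. Without the replicate 1 pair 0 passed too, with 536 unadjusted, and the smallest adjusted p was 0.331, shared by Neb at -0.93 ± 0.13 (SE), Dapl1 at -1.63 ± 0.24 (SE) and Chil5 at -1.77 ± 0.23 (SE). Chil5 has near-identical relatives, so its value is uncertain.

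By gene list, most cell cycle genes were higher and most resting T cell genes lower in CD25+ libraries without PTEN. With the estimated correlation 0 lists passed in this contrast. Cell cycle genes were higher in 36 of 39 (median 0.17, adjusted p 2.53e-10), among them Ccnb2 at 0.51 ± 0.18 (SE) and Prc1 at 0.48 ± 0.17 (SE), and resting and naive genes lower in 17 of 19 (median -0.19, adjusted p 2.64e-06). Their adjusted p with the estimated correlation were 0.634 and 0.515. Both held without the pair, with cell cycle genes higher in 39 of 39 (median 0.20, adjusted p 2.13e-11) and resting genes at -0.27 (adjusted p 1.45e-12), each with an adjusted p of 0.295 with the estimated correlation. Erythroid and platelet markers were lower with the pair (7 of 7, -0.17, adjusted p 0.000439, or adjusted p 0.515 estimated) and without it (-0.12, adjusted p 0.0176, or adjusted p 0.295 estimated). Over all genes 0 members of any list passed in limma, and adjusted over the list alone Il7r, Dapl1 and Txk passed among resting genes.

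Other lists called in the CD25+ gate were not called without the pair. Effector Treg genes (23 of 26, median 0.29, adjusted p 6.92e-06), follicular T cell genes (19 of 24, 0.21, adjusted p 0.000439), Th1 and cytotoxic genes (14 of 19, 0.15, adjusted p 0.0106), glycolysis (15 of 19, 0.12, adjusted p 0.0118) and co-inhibitory receptors (9 of 13, 0.11, adjusted p 0.0409) were higher, with adjusted p of 0.634, 0.712, 0.634, 0.741 and 0.634 with the estimated correlation. None of their members passed adjusted over the list alone. Examples were Cxcr5, the receptor for the follicle chemokine, at 0.88 ± 0.38 (SE), Bcl6, the regulator of follicular T cells, at 0.71 ± 0.32 (SE) and Pdcd1 at 0.74 ± 0.44 (SE). Without it these 5 lists were at -0.025 (adjusted p 0.901), -0.015 (adjusted p 0.375), 0.043 (adjusted p 0.273), -0.032 (adjusted p 0.901) and -0.025 (adjusted p 0.385). In their place FOXO1 targets (-0.18, adjusted p 0.000213), chemokine receptors and homing (-0.19, adjusted p 0.00308), conventional T cell genes (-0.11, adjusted p 0.00164) and PI3K-AKT-mTOR components (-0.12, adjusted p 0.0432) were lower. Oxidative phosphorylation (0.094, adjusted p 0.00164) and markers of B cells (0.060, adjusted p 0.0205), myeloid cells (0.014, adjusted p 0.0456) and CD8 and NK cells (0.0071, adjusted p 0.0317) were higher. The smallest adjusted p of these was 0.295 with the estimated correlation.

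In libraries labelled CD25-, the question was the same for Tregs sorted for little surface CD25. PTEN-deficient cells had less Dapl1 and Atp6v0d2 than WT cells. Dapl1 fell by 2.13 ± 0.23 (SE, adjusted p 0.0365), from 10.59 ± 0.26 (SD, n = 3) to 8.46 ± 0.38 (SD, n = 2). Atp6v0d2, a subunit of the vacuolar proton pump, fell by 1.40 ± 0.16 (SE, adjusted p 0.0365), from 6.31 ± 0.25 (SD, n = 3) to 4.91 ± 0.23 (SD, n = 2), which is dim. These were the 2 genes past the threshold, and 642 had an unadjusted p under 0.05. Neither passed after a shift of each array to a common median (smallest adjusted p 0.0748), after quantile normalization (smallest adjusted p 0.078) or in a fit to the arrays compared alone (smallest adjusted p 0.328). Both groups' arrays did not overlap for either gene, as in 16.1% of all genes, where chance gives 20%. The naming rule asks for this gap, so it adds no support. The largest higher value was Penk at 2.05 ± 0.27 (SE, adjusted p 0.103), with 11.02 ± 0.26 (SD, n = 2) in PTEN-deficient and 8.97 ± 0.39 (SD, n = 3) in WT libraries. Foxp3 was at 0.31 ± 0.15 (SE) and Il2ra at 1.18 ± 0.65 (SE). Without the pair, which leaves 1 PTEN-deficient CD25- library, 0 genes passed in limma and 523 had an unadjusted p under 0.05. Dapl1 was then at -1.86 ± 0.27 (SE), Atp6v0d2 at -1.24 ± 0.20 (SE), Penk at 1.86 ± 0.29 (SE) and Gzmb, the cytotoxic protease granzyme B, at 1.01 ± 0.15 (SE), each with an adjusted p of 0.432. The 2 calls also depended on single libraries: without any of 8 of the 10 arrays 0 genes passed, and Dapl1 alone passed without PTEN-deficient CD25+ replicate 3. Without the library labelled PTEN-deficient CD25+ replicate 1, 5 passed: Dapl1 and Atp6v0d2 lower, and Gjb2, Naip6 and Penk higher.

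Resting T cell genes and FOXO1 targets were lower in PTEN-deficient CD25- libraries, and the Treg core signature was higher. Resting and naive genes were lower in 16 of 19 (median -0.30, adjusted p 1.43e-11, and adjusted p 0.238 with the estimated correlation). Over all genes 1 of them passed (Dapl1), and adjusted over the list alone 8 did, among them Klf2, the regulator of lymphocyte exit and quiescence, at -0.54 ± 0.13 (SE) and Actn1 at -0.36 ± 0.11 (SE). FOXO1 targets were lower in 14 of 18 (median -0.21, adjusted p 1.66e-06, and adjusted p 0.238 with the estimated correlation), with 0 past the threshold over all genes and Klf2 and Il7r adjusted over the list alone. Il7r was at -0.94 ± 0.14 (SE) and Pik3ip1 at -0.65 ± 0.22 (SE). Without the pair resting genes were at -0.35 (18 of 19 lower, adjusted p 1.3e-21) and FOXO1 targets at -0.33 (adjusted p 1.47e-09), each with an adjusted p of 0.233 with the estimated correlation. The Treg core signature was higher in 23 of 27 (median 0.41, adjusted p 7.34e-11, and adjusted p 0.238 with the estimated correlation), with 0 past the threshold over all genes and Tnfrsf18, Tnfrsf4, Tnfrsf9 and Penk adjusted over the list alone. Tnfrsf18 (GITR), Tnfrsf9 (4-1BB) and Tnfrsf4 (OX40), costimulatory receptors of activated Tregs, were at 0.61 ± 0.15, 0.78 ± 0.21 and 0.77 ± 0.23 (SE). Without the pair this list was at 0.23 (adjusted p 4.6e-05, and adjusted p 0.526 with the estimated correlation). Conventional T cell genes were lower with the pair (-0.079, adjusted p 0.00115, or adjusted p 0.316 estimated) and without it (-0.13, adjusted p 7.06e-05, or adjusted p 0.417 estimated), with Dapl1 past the threshold over all genes and Dapl1 and Il7r adjusted over the list alone. Of markers of other cells in this gate, Slamf7 was at 0.96 ± 0.15 (SE, adjusted p 0.254), past the threshold adjusted over the plasma cell list alone, and Lyz2 at 1.13 ± 0.33 (SE, adjusted p 1), while no list of other cells was called.

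Further lists in the CD25- gate were cell cycle genes, higher in 30 of 39 (median 0.21, adjusted p 1.65e-05) with Mcm3 at 0.47 ± 0.16 (SE) and Ccna2 at 0.68 ± 0.29 (SE), and oxidative phosphorylation, higher in 20 of 27 (0.16, adjusted p 0.0175). Immediate early and sorting stress genes (-0.15, adjusted p 0.00589), chemokine receptors and homing (-0.21, adjusted p 0.00567), PI3K-AKT-mTOR components (-0.080, adjusted p 0.00388) and Th17 genes (-0.095, adjusted p 0.0491) were lower. These 6 had, with the estimated correlation, adjusted p of 0.62, 0.682, 0.587, 0.62, 0.682 and 0.525. Over all genes 0 of their members passed, and adjusted over the list alone only Gpr15, a gut homing receptor, at -1.01 ± 0.23 (SE), and Ccr8, a chemokine receptor of activated Tregs, at 0.92 ± 0.24 (SE). Without the pair cell cycle genes were not called (0.054, adjusted p 0.838), nor were oxidative phosphorylation (0.042, adjusted p 0.838), chemokine receptors (-0.027, adjusted p 0.303), PI3K-AKT-mTOR components (-0.029, adjusted p 0.0921) or Th17 genes (-0.078, adjusted p 0.142). Immediate early genes stayed called (-0.15, adjusted p 0.00516). Effector Treg (0.16, adjusted p 1.12e-05), follicular T cell (0.32, adjusted p 1.53e-07) and co-inhibitory receptor lists (0.13, adjusted p 0.000934) were then higher, where with the pair they were at -0.28, -0.14 and 0.066 and not called. These 4 had an adjusted p of 0.417 with the estimated correlation.

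**Figure D3:**
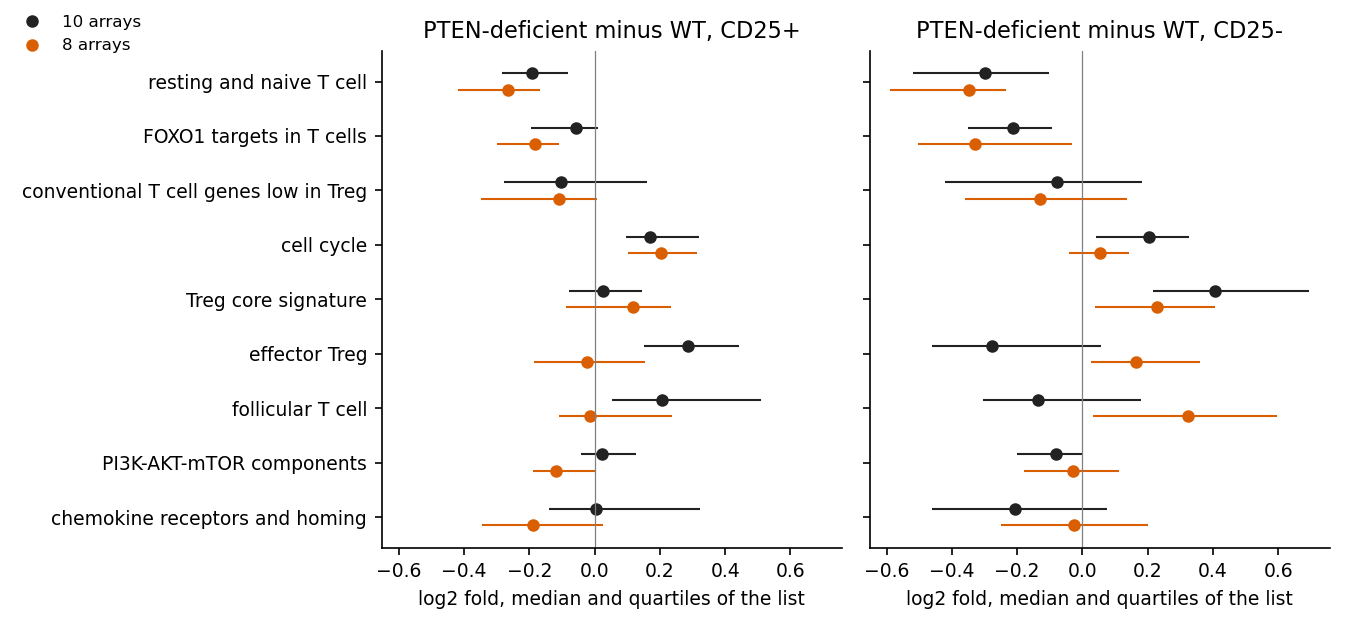
Log2 difference PTEN-deficient minus WT of 9 gene lists in CD25+ (left) and CD25- libraries (right), with all 10 arrays (black) and with the 8 left without the PTEN-deficient replicate 1 pair (orange); points are the median and bars the quartiles over the list's genes. Resting and naive T cell genes lie below 0 in all 4 comparisons (-0.19 and -0.27 in CD25+, -0.30 and -0.35 in CD25-), while effector Treg genes move from 0.29 to -0.025 in CD25+ and from -0.28 to 0.16 in CD25-.

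Genotype folds of the gates shared 0 called genes with all arrays and without the pair, and the CD25+ gate had no calls to share. Across genes, which are not independent replicates, the correlation of the folds was -0.03 with all arrays and 0.21 without the pair.

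What separates CD25- from CD25+ Tregs in WT mice was tested next. Neb fell by 1.27 ± 0.11 (SE, adjusted p 0.00484) in CD25- cells, from 8.63 ± 0.17 (SD, n = 2) to 7.36 ± 0.03 (SD, n = 3), and was the 1 gene past the threshold with all arrays, against 1824 with an unadjusted p under 0.05. Il2ra was at -2.11 ± 0.65 (SE, adjusted p 0.485) and Foxp3 at -0.11 ± 0.15 (SE). Without the pair the WT folds are the same by construction, but each gene's spread is estimated anew. It fell for some genes, such as Penk (SE 0.27 to 0.23), and rose for others, such as Neb (SE 0.11 to 0.12). In that fit 80 genes passed, 38 higher and 42 lower in CD25- cells, with 2507 unadjusted. The pair was left out because it went against this gate difference. Neb did not pass without WT CD25+ replicate 1, WT CD25- replicate 2 or WT CD25- replicate 3, with adjusted p up to 0.16.

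Il2ra was among the 80 genes, while the IL-2 and STAT5 list as a whole was not called without the pair (12 of 24 genes above 0, adjusted p 0.943). Il2ra fell by 2.11 ± 0.34 (SE, adjusted p 0.0433). Socs2, a STAT5 target, fell by 1.92 ± 0.18 (SE, adjusted p 0.00558), from 10.04 ± 0.07 (SD, n = 2) to 8.12 ± 0.32 (SD, n = 3), and Myc fell by 1.62 ± 0.16 (SE, adjusted p 0.00829). Dctd, Car12, Ifitm3, Naf1 and Gpr34 fell too, at -1.77, -1.71, -1.79, -1.68 and -1.66. Ccl5 rose by 1.82 ± 0.17 (SE, adjusted p 0.00558), S100a4 by 1.78 ± 0.17 (SE, adjusted p 0.00558), the Th1-associated receptor Cxcr3 by 1.5 ± 0.17 (SE, adjusted p 0.0124), from 8.98 ± 0.32 (SD, n = 2) to 10.47 ± 0.13 (SD, n = 3), and the integrin Itgb1 by 1.36 ± 0.16 (SE, adjusted p 0.0143). Myo1f, Pde3b, Anxa2 and Tox2 rose by 1.70, 1.53, 1.47 and 1.33. For all of these the 3 CD25- arrays lay apart from the 2 CD25+ arrays, as in 28.7% of all genes, where chance gives 20%. The naming rule asks for this gap, so it adds no support. A fit to the 5 WT arrays alone called 31 genes, 25 of them among the 80.

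By list, effector Treg genes were higher in CD25- WT cells in 23 of 26 (median 0.57, adjusted p 1.1e-08 with all arrays and adjusted p 6.56e-20 without the pair). For each list called in this contrast the adjusted p with the estimated correlation was 0.56 with all arrays and at least 0.201 without the pair. Without the pair 9 members passed over all genes and 17 adjusted over the list alone, among them Ccr2 at 1.32 ± 0.16 (SE). Follicular T cell genes followed (20 of 24, 0.54, adjusted p 1.33e-06 and adjusted p 5.62e-12), with 2 (Tox2 and Maf) over all genes and 15 adjusted over the list alone. Chemokine receptors and homing were at 0.49 (19 of 26, adjusted p 1.69e-05 and adjusted p 5.74e-11), with 6 over all genes and, adjusted over the list alone, 15 higher and 1 lower (Ccr6). Th1 and cytotoxic genes were at 0.19 (15 of 19, adjusted p 0.000802 and adjusted p 3.62e-06), with 3 over all genes (Ccl5, Cxcr3 and Cxcr6) and 6 adjusted over the list alone. The Treg core signature was lower in 21 of 27 (-0.22, adjusted p 0.00427 and adjusted p 0.000478). Of its members Il2ra, Socs2, Gpr83 and Plagl1 passed over all genes, and adjusted over the list alone 7 were lower and 3 higher (Nrp1, Tigit and Icos). With all arrays 0 members of these lists passed in limma over all genes, and adjusted over the list alone Gpr83 and Penk did.

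Metabolic and signalling lists were also higher in CD25- WT cells: glycolysis (15 of 19, median 0.26, adjusted p 0.000392), immediate early and sorting stress (22 of 27, 0.28, adjusted p 8.7e-05), PI3K-AKT-mTOR components (23 of 27, 0.12, adjusted p 0.00105) and sterol and fatty acid synthesis (18 of 22, 0.12, adjusted p 0.00447). All 4 stayed called without the pair (adjusted p 0.000101, 0.000143, 0.0002 and 0.00466), with Sgk1, a kinase of the PI3K pathway, higher by 0.86 ± 0.11 (SE) and Rgs1 at -1.03 ± 0.15 (SE) past the threshold over all genes. Adjusted over the list alone they had 0, 4, 3 and 0 members, and with the estimated correlation adjusted p of 0.493, 0.291, 0.493 and 0.499. FOXO1 targets were called without the pair (0.13, adjusted p 0.0362, and adjusted p 0.493 with the estimated correlation) and not with it (adjusted p 0.0619). The IL-2 and STAT5 list was not called (0.0037, adjusted p 0.876). Its mean was -0.141 although the test pointed up, and adjusted over the list alone Il2ra, Socs2, Bcl2 and Myc were lower with all arrays.

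The same gate comparison in PTEN-deficient mice gave 0 genes past the threshold in limma with the labels as given, and 477 with an unadjusted p under 0.05. Il2ra was at -0.35 ± 0.65 (SE) and Foxp3 at 0.19 ± 0.15 (SE). The smallest p belonged to Zfp931 at -1.19 ± 0.18 (SE, adjusted p 0.904), Dcun1d5 at -1.01 ± 0.19 (SE), Thap6 at -0.69 ± 0.13 (SE) and, on the higher side, the olfactory receptor Olfr767 at 1.06 ± 0.23 (SE). None of the 26 lists was called, the smallest camera adjusted p being 0.0895 for glycolysis. The within-group SD of Socs2 was 0.95 (n = 3) in libraries labelled CD25+ and 1.40 (n = 2) in those labelled CD25-, against 0.07 (n = 2) and 0.32 (n = 3) in WT.

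Without the replicate 1 pair, 29 genes passed in PTEN-deficient cells, 17 higher and 12 lower in the 1 remaining CD25- library, and 1798 had an unadjusted p under 0.05. Myo1f rose by 2.07 ± 0.25 (SE, adjusted p 0.0305), Cxcr3 by 1.88 ± 0.22 (SE, adjusted p 0.0305), S100a4 by 1.86 ± 0.22 (SE, adjusted p 0.0305), the cytokine Il4 by 1.68 ± 0.22 (SE, adjusted p 0.0306) and Gzmb by 1.66 ± 0.16 (SE, adjusted p 0.0182). Tox2, Ccl5 and Ccr2 rose by 1.94, 1.70 and 1.63. Socs2 fell by 1.95 ± 0.24 (SE, adjusted p 0.0305), Car12 fell by 1.97 ± 0.17 (SE, adjusted p 0.0182) and Myc fell by 1.53 ± 0.22 (SE, adjusted p 0.044). Dctd, Gsta4, Tlr7, Fsd1l and Cd24a fell too, at -1.91, -1.91, -1.47, -1.47 and -1.22. Il2ra was at -1.89 ± 0.45 (SE, adjusted p 0.199). Cd22, a B cell marker, rose by 1.33 ± 0.17 (SE, adjusted p 0.0306), while the B cell list as a whole was at -0.082 (adjusted p 0.252). Of the lists called in WT, those also called here, with the pair left out for going against the WT gate difference, were effector Treg (0.91, adjusted p 2.63e-24), follicular T cell (0.79, adjusted p 1e-16), chemokine receptors (0.67, adjusted p 3.68e-12), Th1 and cytotoxic (0.37, adjusted p 4.15e-06), glycolysis (0.41, adjusted p 1.38e-06), PI3K-AKT-mTOR components (0.27, adjusted p 0.000538) and sterol synthesis (0.27, adjusted p 0.0146). Co-inhibitory receptors (0.22, adjusted p 0.00116) were higher too, and cell cycle (-0.16, adjusted p 4.69e-05) and oxidative phosphorylation (-0.10, adjusted p 0.0174) lower. No adjusted p with the estimated correlation was below 0.143. Over all genes 6, 3, 3 and 2 members of the first 4 lists passed and 0 of the others. Adjusted over the list alone these 4 had 18 higher, 14 higher and 1 lower (Cd200), 16 higher and 1 lower (Ccr6), and 8 higher, and glycolysis and co-inhibitory receptors had 4 each.

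Of the 80 and the 29 genes, 18 passed in both genotypes. Independent lists would share 0.0327 higher and 0.0255 lower ones, but this is no fair comparison, since the pair was left out because it went against the WT gate difference, which favours agreement between the genotypes. There were 12 higher genes, Ccl5, S100a4, Myo1f, Cxcr3, Itgb1, Tox2, Ccr2, Il9r, Cdc25b, Nav2, Maf and Gzmb, and 6 lower ones, Socs2, Dctd, Car12, Myc, Tlr7 and Fsd1l. Some of these fall outside the naming rule and are given to complete the overlap. By list, the Treg core signature, FOXO1 targets and immediate early and sorting stress were called without the pair in WT libraries only. Across all genes, which are not independent replicates, the folds correlated with r = 0.68 without the pair, under the same reservation, and with r = 0.32 with all arrays, where 0 calls were shared.

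**Figure D4:**
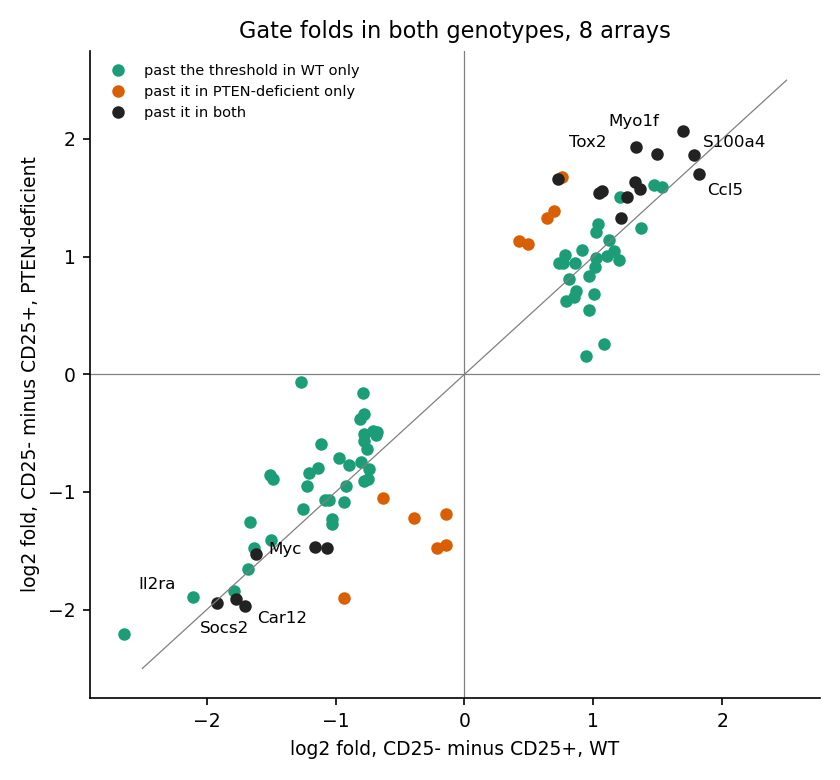
Log2 difference CD25- minus CD25+ in WT (horizontal) and PTEN-deficient libraries (vertical) without the PTEN-deficient replicate 1 pair; points are the genes past the threshold in WT (80), PTEN-deficient cells (29) or both (18, black), and the diagonal marks equal folds. The vertical values rest on 1 CD25- library, and leaving out the pair favours agreement between the axes.

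Whether PTEN loss acted differently in the gates was tested by the interaction, the genotype difference in CD25- minus that in CD25+ libraries. In limma 0 genes passed, and 462 had an unadjusted p under 0.05. Neb had the smallest p, at 1.19 ± 0.15 (SE, adjusted p 0.247) and at 1.21 ± 0.20 (SE, adjusted p 1) without the pair. The gate difference of Neb was -1.27 in WT and -0.06 ± 0.16 (SE) in PTEN-deficient libraries without the pair. Atp6v0d2 was at -0.99 ± 0.23 (SE, adjusted p 1), Gpr52 at 1.38 ± 0.24 (SE), Stom at -1.05 ± 0.23 (SE), Il2ra at 1.76 ± 0.91 (SE) and Foxp3 at 0.30 ± 0.21 (SE). Without the pair 0 genes passed and 292 had an unadjusted p under 0.05.

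With all arrays 8 lists were called in the interaction. The Treg core signature was positive (22 of 27, median 0.35, adjusted p 0.00019), with Penk at 1.5 ± 0.39 (SE) and Gpr83 at 1.54 ± 0.51 (SE). Effector Treg (-0.48, adjusted p 6.23e-05), follicular T cell (-0.43, adjusted p 0.00367), Th1 and cytotoxic (-0.24, adjusted p 0.0056), PI3K-AKT-mTOR components (-0.12, adjusted p 0.00356), FOXO1 targets (-0.18, adjusted p 0.0409), immediate early and sorting stress (-0.14, adjusted p 0.00367) and chemokine receptors and homing (-0.41, adjusted p 0.00367) were negative, with S100a4 at -1.67 ± 0.92 (SE) and Ccl5 at -1.70 ± 0.82 (SE). With the estimated correlation each had an adjusted p of 0.744, and 0 members passed over all genes or adjusted over the list alone. Without the pair 0 of the 8 were called in the same direction, and 5 lists were called: effector Treg (0.27, adjusted p 0.00062) and follicular T cell (0.29, adjusted p 0.000761) positive, and cell cycle (-0.14, adjusted p 5.31e-07), resting and naive (-0.10, adjusted p 0.0455) and myeloid and dendritic markers (-0.080, adjusted p 0.0215) negative. Their adjusted p with the estimated correlation were at least 0.742, 0 members passed over all genes, and Gzmb passed adjusted over the effector Treg list alone.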

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

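Of the tests in this part, the splits of genotype and the quantile normalization for Dapl1 and Il7r were chosen beforehand, while all uses of the gate score, the splits of the gate, and the fits without the PTEN-deficient replicate 1 pair were chosen only after the results were seen.

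In 8 gene lists the genotype difference differed between the gates by the interaction test. Their medians were 0.346 for the Treg core signature (camera adjusted p 0.00019), -0.478 for effector Treg (adjusted p 6.23e-05), -0.434 for follicular T cell (adjusted p 0.00367), -0.243 for Th1 and cytotoxic (adjusted p 0.0056), -0.123 for PI3K-AKT-mTOR components (adjusted p 0.00356), -0.177 for FOXO1 targets (adjusted p 0.0409), -0.137 for immediate early and sorting stress (adjusted p 0.00367) and -0.410 for chemokine receptors and homing (adjusted p 0.00367). Each had an adjusted p of 0.744 with the estimated correlation.

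A candidate explanation for these 8 lists is the gate labels of the replicate 1 pair of PTEN-deficient libraries. Without the pair, 0 of the 8 lists passed in the same direction, and 5 of them pointed the opposite way, with effector Treg at 0.267 and follicular T cell at 0.286 past the threshold. The Treg core signature at 0.134 and FOXO1 targets at -0.068 kept their direction and did not pass. Immediate early and sorting stress kept the direction of its test without passing, though its median was then 0.0022. A true difference of the PTEN effect between gates stays open for the lists called without the pair, since these rest on 1 PTEN-deficient CD25- library and did not pass with the estimated correlation (adjusted p 0.742).

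The replicate 1 pair itself had gate scores against its labels, and an exchange of the 2 labels is a candidate explanation for these scores: 0.983 for the library labelled CD25+ and 0.191 for the one labelled CD25-. A large mixture of cells in the library labelled CD25+ is argued against by its lower quartile of 0.856 over 50 genes. The quartile is a spread over genes and not a share of cells, so a small mixture stays open. Differences in distribution left between arrays after RMA are argued against by its score of 0.976 after quantile normalization, which does not test other array effects. A shift of all PTEN-deficient CD25+ cells towards the CD25- profile is argued against by the other 2 libraries, whose highest score was 0.134. For the library labelled CD25- some mixture stays open, since its quartiles were -0.072 and 0.442, 11 of 50 gate genes lay nearer to the WT CD25- mean, and so did its Cd4 of 11.39 (WT means 11.82 for CD25- and 10.59 for CD25+). Of the 10 splits of the 5 PTEN-deficient arrays into 3 and 2, the one that exchanges these labels gave 376 genes past the threshold, the labels as given 0 and the other 8 splits 0, which points to a structure of the samples already seen in their gate scores and adds no separate support; 10 splits are too few for a share under 0.05. An unusual animal, with both of its sorted populations out of place, was not tested.

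Lower Dapl1 and Il7r in PTEN-deficient libraries was the genotype result with 2 genes past the threshold over both gates. If each array counts as independent, chance is argued against, with all arrays, by the splits of genotype within gates. Of 100 splits 1, the real one, gave 2 genes, and the highest of the others gave 0. The labels do not say which animal gave which array, and arrays that share an animal would not be independent. No smaller share was possible with 100 splits, and this contrast was 1 of 6. The splits used all arrays, so they do not cover the fit without the pair, where 0 genes passed. Scaling is argued against by quantile normalization, after which the larger adjusted p of both genes was 0.00555. For the labels of the pair, the upper 95% bound nearest to 0 of the folds without it was -0.718. This bound cannot decide whether the calls rest on those labels. Both genes were picked for their small p with all arrays, and the fit without the pair reuses the remaining ones. Without the pair the folds were -1.74 ± 0.18 (SE) for Dapl1 and -1.0 ± 0.12 (SE) for Il7r, against -1.84 ± 0.16 (SE) and -1.03 ± 0.10 (SE) with it, and the calls ended (adjusted p 0.0831 and 0.108) with 4 residual degrees of freedom in place of 6. A change within each cell, a lower share of resting cells in the sorted populations and a batch that the labels do not give stay open, since none of them was tested.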

How the results depend on the processing

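The tests in this part were chosen beforehand except those without the PTEN-deficient replicate 1 pair, which were chosen only after the results were seen. Over the alternatives chosen beforehand, other than leaving out arrays, 58 counts stayed within 1.5 times and 12 moved; of the values of named genes 3991 stayed on their side of the threshold, among them 41 below it that changed sign, 22 gained the threshold and 9 lost it. Of the gene lists 457 stayed, among them 14 not called that changed direction, 11 gained the call and 85 lost it (46 of them with the estimated correlation). Dapl1 and Il7r passed in the averaged genotype contrast in 8 of 8 of these alternatives (adjusted p 0.00151 to 0.0137 and 0.00264 to 0.0138). Neb passed in the WT gate contrast in 8 of 9 (adjusted p 0.00245 to 0.0561), and in the CD25- genotype contrast Dapl1 in 5 of 9 (0.0119 to 0.328) and Atp6v0d2 in 4 of 8 (0.0119 to 0.56). Limits are 2 to 3 arrays per group, and array signal that holds background without detection calls, which leaves dim genes such as Atp6v0d2 uncertain; it was not tested among the brighter genes.

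The CD25- genotype count of 2 became 1 (Dapl1) among the brighter genes alone, 0 after the median shift, 0 after quantile normalization, 0 with only the arrays compared and 0 without the pair. Array weights gave 3 genes in the CD25+ genotype contrast (Dapl1, Il7r and Neb, lower), 1 in the PTEN-deficient gate contrast (Zfp931), 10 in the averaged contrast (Actg2, Gjb2, Naip6 and Penk higher, Atp6v0d2, Cd55, Dapl1, Il7r, Prg4 and St8sia6 lower) and 1 gene shared between the genotype calls (Dapl1). The WT gate count of 1 became 31 with only the arrays compared and 80 without the pair. With the pair left out the PTEN-deficient gate count was 29, the gate calls shared 18 and the averaged count was 0. The larger WT gate counts follow from the estimate of spread, since the WT folds are identical in these fits; the SE of Il2ra in WT went from 0.65 to 0.34 without the pair. In the PTEN-deficient gate contrast the folds changed as well, with Il2ra at -0.35 with all arrays and -1.89 without the pair. For the others the cause was not tested.

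With the replicate number as a fixed block, the CD25- genotype count was 0 and the WT gate count 0, while Dapl1 and Il7r passed in the averaged contrast. With the random replicate block the averaged count was 4 (Atp6v0d2, Cd55, Dapl1 and Il7r), and no other count moved. The labels name no animal for a number. Deviations from the group means of arrays with the same number correlated at -0.50, -0.37, 0.03 and 0.31 within a genotype, at -0.23 to 0.12 within a gate, and across both at 0.33, 0.44 and 0.25 for PTEN-deficient CD25+ with WT CD25- and 0.01 and 0.01 for PTEN-deficient CD25- with WT CD25+. Of 10 arrays 5 matched their own number best outside their group, and the consensus correlation was -0.166. In groups of 2 arrays deviations mirror each other, and the labels of the replicate 1 pair are in doubt, so these values do not settle whether the numbers pair the arrays. Groups that differ in gate or genotype alone share 2 numbers each, and the numbers were not taken as pairs because the labels tie them to no animal, batch or day.

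Leaving out 1 array at a time gave 0 to 1 genes in the WT gate contrast, 0 to 5 in the averaged genotype contrast and 0 to 5 in the CD25- genotype contrast, the 5 each without the library labelled PTEN-deficient CD25+ replicate 1. Lists that passed with all arrays or with 1 left out, and had the opposite direction in the other fit, turned without 1 of 3 libraries, those labelled PTEN-deficient CD25+ replicate 1, CD25- replicate 1 or CD25- replicate 3. Their medians over the arrays left out ranged, in the CD25+ genotype contrast, from -0.119 to 0.0603 for B cell markers, -0.189 to 0.195 for chemokine receptors, -0.0319 to 0.328 for glycolysis and -0.118 to 0.162 for PI3K-AKT-mTOR components. In the CD25- genotype contrast they ranged from 0.0540 to 0.356 for cell cycle, where the test and not the median turned, -0.705 to 0.164 for effector Treg and -0.429 to 0.324 for follicular T cell. For the PTEN-deficient gate the ranges were -0.148 to 0.135 for cell cycle, -0.195 to 0.616 for effector Treg, -0.156 to 0.559 for follicular T cell, -0.0988 to 0.159 for PI3K-AKT-mTOR components and -0.309 to 0.314 for Th1. For the interaction they were -0.203 to 0.256 for cell cycle and -0.847 to -0.0200 for follicular T cell, and for the averaged contrast -0.00902 to 0.179 for glycolysis. Without the whole pair the reversed values were 1.63 for Ccr2 in the PTEN-deficient gate, 0.275 for PI3K-AKT-mTOR components there, -0.0319, -0.118, -0.189 and 0.0603 for glycolysis, PI3K-AKT-mTOR, chemokine receptors and B cell markers in the CD25+ genotype contrast, 0.0540, 0.164 and 0.324 for cell cycle, effector Treg and follicular T cell in the CD25- one, and 0.267, 0.286, 0.0891, 0.0943 and 0.198 for effector Treg, follicular T cell, Th1, PI3K-AKT-mTOR and chemokine receptors in the interaction. Gene lists were not run with the random block, which camera does not take, nor with array weights or only the arrays compared.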

Other observations

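The count of splits and the genes below were chosen only after the results were seen. Several genes kept the genotypes wholly apart, all 5 PTEN-deficient arrays on 1 side of all 5 WT arrays. Besides Dapl1, Il7r, Penk and Atp6v0d2 these included genes outside the fixed lists, such as Scp2, a lipid transfer protein, at 5.72 ± 0.29 (SD, n = 5) without PTEN and 6.63 ± 0.65 (SD, n = 5) in WT, and Lgmn, a lysosomal protease that degrades Foxp3 protein, at 7.17 ± 0.28 (SD, n = 5) and 7.86 ± 0.13 (SD, n = 5). Tsc22d3, the glucocorticoid-induced leucine zipper and a FOXO target, was at 8.39 ± 0.14 (SD, n = 5) and 8.92 ± 0.24 (SD, n = 5). Higher without PTEN was Gjb2, a gap junction protein, at 7.18 ± 0.22 (SD, n = 5) against 6.43 ± 0.26 (SD, n = 5). In all 86 genes were wholly apart, 43 higher and 43 lower, where chance gives on average 0.794% or 157 genes. Of 126 splits of the 10 arrays into 5 and 5, 44 gave at least as many. Splits other than the real one had a median of 56 genes and a highest of 1523. The number of such genes therefore does not stand out from chance.

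Single genes of migration and activation went both ways in the values averaged over both gates without the PTEN-deficient replicate 1 pair, where 0 genes passed in limma and 688 had an unadjusted p under 0.05. Among immediate early genes, 17 below 0 and 10 above, Jun was at -0.99 ± 0.19 (SE) and Klf6 at -0.51 ± 0.10 (SE) but Nr4a2 at 0.38 ± 0.12 (SE). Among chemokine receptors and homing genes, 18 below 0 and 8 above, Gpr15 was at -0.69 ± 0.12 (SE) and Cxcr4 at -0.62 ± 0.17 (SE) but Cxcr5 at 0.69 ± 0.17 (SE) and Ccr8 at 0.76 ± 0.18 (SE). The effector Treg list had 16 genes above 0 and 10 below, with Gzmb at 0.55 ± 0.10 (SE).

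The 3497 probe sets with several gene symbols or none were tested apart. With all arrays 0 passed in limma in any of the 6 contrasts, with 50, 83, 277, 80, 70 and 72 at an unadjusted p under 0.05 (in the order CD25+ genotype, CD25- genotype, WT gate, PTEN-deficient gate, interaction and averaged genotype). Without the pair 3 passed in the WT gate contrast and 4 in the PTEN-deficient one. They carry no single gene name and are not analysed further here.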
